A study of Arabidopsis thaliana with 18 samples.

How the data were processed

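Rosette leaves of Arabidopsis thaliana were compared in 6 groups of 3 libraries, formed by 3 genotypes (WT Col-0, jar1-11 and JAR1-OE) and 2 conditions (watered or left without water). Groups were taken from the labels of each sample. Libraries were numbered 1 to 3 within each group in the order of the labels, whose own numbers run on from control to drought. Per the labels' protocols, RNA was made into libraries with a QuantSeq 3' mRNA kit, which gives reads near the 3' ends of transcripts, and sequenced on an Illumina HiSeq instrument. The deposited values are counts, which per the file headers are the whole numbers of unique reads of each gene. The aligner, the counter and the genome build behind them are not given in the sources used here. Each file held 27655 genes and 1 further entry, the YFP-JAR1 transgene of 732 bases, which was kept out of library totals and tests. Of the gene identifiers 27433 were matched to the TAIR10.1 reference, and 27432 of these had a length equal to their span there, which gave symbols and the position of JAR1.

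Library totals ran from 4716155 to 9506727 reads. Where a group had 0 reads of a gene, folds were computed against a floor of 3 reads over the group, which covers counting error only, since no molecular identifiers are described for these reads. Where a group had 1 to 3 reads, the fold of pooled reads was given with an exact binomial 95% interval. Medians of lists were also computed with genes at 0 reads in a group set to their bound, or to 0 where none can be given. For differences of response the bound put the floor in place of the group at 0, and limits of groups with 1 to 3 reads came from the exact Poisson 95% interval of that group's reads alone. Only reads mapped to 1 place were given, so genes with near-identical copies, such as the RBCS and PDF1.2 families, are uncertain, and so are overlapping and antisense genes, as the strand setting of the counting is not given in the sources used here. Replicates of a group differed by a chi-square per degree of freedom of 5.78 to 29.9 over 18 pairs, far from a repeat of 1 library under 2 names.

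The tests were set before the data were examined. Counts were scaled by TMM and filtered with filterByExpr, which left 17678 genes (9977 were not tested), and fitted in edgeR 4.0.16 (R 4.3.3) with 1 mean per group over all 18 libraries. The quasi-likelihood F-test was used for 9 contrasts, with Benjamini-Hochberg adjustment within each and a threshold of 0.05. These were drought against control in each genotype, each altered line against WT in each condition, and the difference of each line's drought response from that of WT. The biological coefficient of variation was 19.8%. SEs were taken as the absolute log2 fold change divided by the square root of F. The 25 gene lists with 330 genes, drawn up from general knowledge, were tested with camera at a preset correlation of 0.01 and again with an estimated one, with adjustment over the lists. Fry was run beside it. The lists were JA biosynthesis, JAZ repressors, JA-Ile and JA turnover, the MYC branch of the JA response, the ERF branch of the JA and ethylene response, ABA synthesis and catabolism, ABA clade A PP2C phosphatases, ABA PYR/PYL receptors, ABA and drought response, proline and raffinose metabolism, nuclear photosynthesis genes, leaf senescence, salicylic acid and pathogenesis, antioxidant enzymes with ascorbate and glutathione metabolism, aliphatic glucosinolates, indolic glucosinolates, flavonoids and anthocyanins, heat shock, aquaporins, expansins, circadian clock, inflorescence and flower markers, root markers, guard cell and stomatal lineage markers and cell division.

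Named genes followed a rule. It took JAR1 and the 6 largest rises and falls per contrast among genes past the threshold with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries (5 each way without the overlap condition for the differences of response). It also took up to 3 members per list with the smallest p where the list had at least 2 called members or a camera call. A gene named in 1 contrast was also given in others. Genes for the size of the drought response came from the genotype outside each comparison, at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Principal components were computed from log2 CPM with a prior count of 2.

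The procedure was tested on simulated data modelled on drought against control in WT, with 17312 genes. It recovered 43.9% of 98 genes changed 2-fold and 90% of 100 changed 4-fold, and 3.62% of its 138 calls were false. Camera found the shifted list and called 0 of 20 unshifted ones. The simulated genes were drawn independently of each other, so this does not test the preset correlation on lists whose members vary together. Alternatives were RLE scaling, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter on low counts, only the groups compared, a replicate block, a fold threshold, no organelle genes (88 chloroplast and 122 mitochondrial), the 200 genes with the smallest p as sets, and leaving out each library. Chosen after seeing the data were leaving out WT control 1 and WT drought 1 together, and a flower marker score of each library as a covariate.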

Results

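Transcript abundance was measured by 3' tag sequencing of rosette leaves from 32-day-old Arabidopsis thaliana. 3 genotypes were compared. WT was the Columbia accession (Col-0), jar1-11 carries a T-DNA insertion in JAR1, and JAR1-OE overexpresses JAR1.1 through a YFP-JAR1 transgene. JAR1 encodes the enzyme that joins jasmonic acid (JA) to isoleucine, and the product JA-Ile is the active hormone. Plants were either watered throughout or left without water for 14 days after 18 days of watering. Each of the 6 groups had 3 libraries, 18 in all. The labels call them biological replicates without saying whether each was a separate plant or a pool, so p-values measure the spread between these libraries. The libraries held 4716155 to 9506727 reads on genes, and 3 reads corresponded to 0.316 to 0.636 CPM (counts scaled to the library's total). Levels of genes are mean CPM with TMM scaling ± SD of 3 libraries, and log2 fold changes are given ± SE. For gene lists, members are those measured, medians are of log2 fold changes, and where 1 direction is given no member passed in the other. Where a group had 1 to 3 reads of a gene, the fold of pooled reads stands in place of the fitted one, with the reads of both groups and the bounds of its 95% counting interval.

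JAR1 (AT2G46370; TAIR10.1, chromosome 2, 19033586 to 19036683) was examined first, since it checks the genotype labels. In WT it stood at 25.3 ± 4.18 CPM with water and 32.9 ± 7.40 CPM under drought. In jar1-11 it stood at 5.69 ± 0.804 and 2.87 ± 1.19 CPM, below WT in each condition (log2 fold change -2.14 ± 0.24, adjusted p = 5.85e-04, and -3.57 ± 0.27, adjusted p = 8.53e-07; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Where the 3' tags lie relative to the insertion is not given in the sources used here. JAR1-OE reached 23.8 ± 3.27 and 33.5 ± 5.02 CPM on the endogenous gene, which differed from WT by less than the spread between replicates (log2 fold change -0.10 ± 0.21, adjusted p = 0.814, and 0.03 ± 0.21, adjusted p = 0.957). The transgene was visible in a separate entry. YFP-JAR1 had 214, 88 and 307 reads in the watered JAR1-OE libraries and 558, 26 and 147 under drought. The other 12 libraries, of genotypes without the transgene, had 0. The pooled level was thus at least 756-fold and 908-fold higher, taking 3 reads over those 12 libraries as the floor. These folds mark the presence of the construct and do not measure how far JAR1 was overexpressed. Pooled and without TMM scaling, the entry stood at 28.8 CPM with water and 34.6 CPM under drought, near the level of the endogenous gene. JAR1-OE drought 2, with 4.21 CPM, carried the least transgene signal of the 6. How reads common to JAR1 and YFP-JAR1 were divided is not given in the sources used here.

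**Figure D1:**
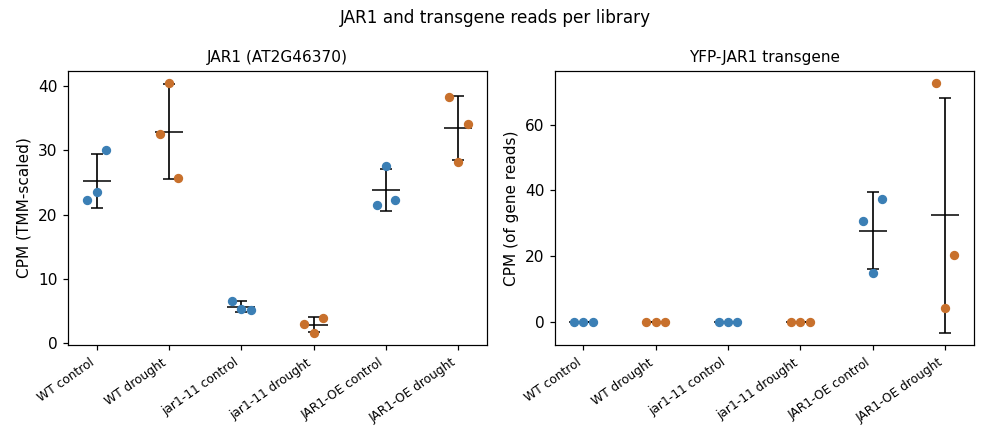
JAR1 and YFP-JAR1 level in CPM on linear axes for each of the 18 libraries, by group. Points are libraries, dashes the group mean and error bars the SD of 3 libraries. JAR1 lies at 5.69 ± 0.804 CPM or lower in jar1-11, and YFP-JAR1 has reads in JAR1-OE alone.

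The first principal component of the 1000 most variable genes held 78.7% of their variance and separated drought from control. Watered libraries scored from -63.7 to -44.3. Among drought libraries JAR1-OE scored 5.62 to 7.34, WT 36.6 to 66.9 and jar1-11 93.5 to 102. WT drought 1 had the lowest WT score, and it also held flower transcripts. PISTILLATA (PI, a petal and stamen identity gene) stood at 18.5 CPM there, against 0 and 0.151 in the other WT drought libraries. In JAR1-OE under drought it stood at 5.80, 15.8 and 7.49 CPM, and in no remaining library above 2.27 CPM. Flower transcripts therefore moved with JAR1-OE under drought and with 1 of 3 WT drought libraries in what follows.

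Drought in WT moved ABA and drought response, clade A PP2C phosphatase and proline metabolism genes up, and aquaporin, expansin, PYR/PYL receptor and photosynthesis genes down, where the expansin and photosynthesis calls did not hold with an estimated correlation. P5CS1, the rate-limiting enzyme of proline synthesis, went from 27.6 ± 3.22 to 1289 ± 344 CPM (log2 fold change 5.55 ± 0.22, adjusted p = 4.23e-12). SWEET15, a sugar transporter of senescing leaves, rose by 9.39 ± 0.45, and the protein phosphatase HAI1, a brake on ABA signalling, by 6.25 ± 0.40. The tonoplast aquaporin TIP1;2 fell from 2975 ± 383 to 142 ± 38.7 CPM (-4.39 ± 0.24), and ORA59, a transcription factor of JA and ethylene defence, changed by -6.14 ± 0.36. Of 17678 genes tested, 6943 passed, 3207 higher and 3736 lower, 3950 of them with an absolute log2 fold change of at least 1.

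Several of the largest changes started from or ended at 0 reads. The invertase-family gene CWINV5 and the small heat shock protein HSP17.4 were at 0 in watered WT and rose to 16.8 ± 4.26 and 15.6 ± 7.31 CPM, at least 100.1-fold and 92.6-fold higher against a floor of 3 reads over the group. So did 3 loci without a symbol in the deposited names, AT4G31830 (at least 134-fold), AT5G07330 (108-fold) and AT5G40790 (99.6-fold). AT5G01300 rose to 64.4 ± 32.1 CPM (1156-fold by 1 and 1327 reads, 207 to 45676). In the other direction AZI1, a lipid transfer-like protein of systemic immunity, fell to 0 (at least 176-fold lower), as did ACT (104-fold), AT5G02760 (109-fold) and the glutaredoxin GRXS11 (96.1-fold). Lower as well were the transporter DTX18 (1070.3-fold by 1 and 932 reads, 192 to 42319) and GASA9, a GASA-family peptide (804-fold by 1 and 700 reads, 144 to 31796).

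In the ABA and drought response list 23 of 25 members rose and 2 fell (23 higher and 2 lower adjusted over the list alone, median 2.39, camera adjusted p = 4.54e-20, adjusted p = 0.0140 with an estimated correlation). HB12 (5.14 ± 0.19), HB7 (4.32 ± 0.24) and LEA4-5 (7.95 ± 0.46) led it. All clade A PP2C phosphatases rose (9 of 9 members, 9 adjusted over the list alone, median 3.92 (3.29 with genes at 0 reads at their bound), camera adjusted p = 7.44e-17, adjusted p = 3.38e-04 with an estimated correlation), with ABI2 at 406 ± 49.1 CPM against 26.8 ± 2.31. The PYR/PYL receptors that bind ABA went the other way, and 6 of 8 members fell (6 adjusted over the list alone, median -2.13, camera adjusted p = 4.07e-12, adjusted p = 0.00209 with an estimated correlation). PYL4 fell from 191 ± 29.7 to 2.88 ± 1.33 CPM. For ABA synthesis and catabolism, 6 of 10 members rose (6 adjusted over the list alone, median 1.1, camera adjusted p = 0.0322, adjusted p = 0.0821 with an estimated correlation), among them the synthesis genes NCED3 (1.29 ± 0.26) and AAO3 (1.51 ± 0.25) and the catabolic CYP707A1 (2.54 ± 0.46). For proline and raffinose metabolism, 7 of 10 members rose and 1 fell (7 higher and 1 lower adjusted over the list alone, median 1.71, camera adjusted p = 4.92e-06, adjusted p = 0.00892 with an estimated correlation), with GOLS2 at 3.37 ± 0.31.

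Photosynthesis genes encoded in the nucleus fell as a group (30 of 34 members, 32 adjusted over the list alone, median -1.12, camera adjusted p = 3.25e-13, adjusted p = 0.0919 with an estimated correlation). RBCS2B (-4.92 ± 0.40), RBCS3B (-2.76 ± 0.25) and PSAH2 (-2.29 ± 0.21) had the smallest p. The RBCS copies are near-identical, so their unique reads are uncertain. For aquaporins 2 of 16 members rose and 14 fell (2 higher and 14 lower adjusted over the list alone, median -2.29, camera adjusted p = 1.29e-08, adjusted p = 0.0297 with an estimated correlation). For the cell wall-loosening expansins 8 of 8 members fell (8 adjusted over the list alone, median -2.29, camera adjusted p = 2.97e-05, adjusted p = 0.0854 with an estimated correlation), with EXPA1 at -4.42 ± 0.48. Aliphatic glucosinolate genes fell too (12 of 14 members, 12 adjusted over the list alone, median -1.70, camera adjusted p = 3.32e-06, adjusted p = 0.117 with an estimated correlation), led by MAM3 (-5.14 ± 0.42) and CYP79F1 (-2.40 ± 0.30). For indolic glucosinolates 4 of 8 members fell (4 adjusted over the list alone, median -1.43, camera adjusted p = 0.0394, adjusted p = 0.406 with an estimated correlation), a call that ended without WT control 3 (adjusted p = 0.0575), WT drought 1 (0.112) or WT drought 3 (0.0548). Flavonoid and anthocyanin genes rose (13 of 14 members, 13 adjusted over the list alone, median 2.43, camera adjusted p = 6.19e-08, adjusted p = 0.0730 with an estimated correlation), including the regulators MYB90 (4.61 ± 0.52) and MYB75 (3.01 ± 0.36). For leaf senescence 8 of 14 members rose and 2 fell (8 higher and 2 lower adjusted over the list alone, median 0.79, camera adjusted p = 0.00288, adjusted p = 0.349 with an estimated correlation). For heat shock 4 of 8 members rose (4 adjusted over the list alone, median 2.19, camera adjusted p = 5.54e-04, adjusted p = 0.0514 with an estimated correlation).

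The JA groups split in WT. In the MYC branch of the JA response 7 of 12 members rose and 2 fell (7 higher and 2 lower adjusted over the list alone, median 1.13, camera adjusted p = 0.194, adjusted p = 0.521 with an estimated correlation). The transcription factor NAC019 rose by 2.98 ± 0.27 and the vegetative storage protein gene VSP2 by 2.62 ± 0.48, of which 1.71 was left without WT drought 1, the library with flower transcripts. MYC4 fell (-1.25 ± 0.21). In the ERF branch shared with ethylene 1 of 7 members rose and 4 fell (1 higher and 4 lower adjusted over the list alone, median -2.70, camera adjusted p = 0.0136, adjusted p = 0.208 with an estimated correlation). Its median was -4.81 without WT drought 1. PDF1.2B (147-fold by 2 and 256 reads, 40.3 to 1220.3), whose copies share sequence, and PR4 (-2.70 ± 0.49) fell beside ORA59. For JA biosynthesis 2 of 12 members rose and 2 fell (1 higher and 2 lower adjusted over the list alone, median 0.31, camera adjusted p = 0.764, adjusted p = 0.888 with an estimated correlation), with ACX1 at 0.93 ± 0.16 and LOX2 at -2.02 ± 0.41. For the JAZ repressors 0 of 11 members passed (0 adjusted over the list alone, median 0.26, camera adjusted p = 0.631, adjusted p = 0.832 with an estimated correlation). For JA-Ile and JA turnover 1 of 9 members rose (1 adjusted over the list alone, median 0.68, camera adjusted p = 0.503, adjusted p = 0.832 with an estimated correlation).

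Among the remaining lists in WT, salicylic acid and pathogenesis genes went both ways, and 4 of 18 members rose and 6 fell (5 higher and 8 lower adjusted over the list alone, median -0.67, camera adjusted p = 0.462, adjusted p = 0.832 with an estimated correlation), with PAD4 at -2.44 ± 0.45. For ascorbate, glutathione and antioxidant enzymes 3 of 19 members rose and 6 fell (3 higher and 6 lower adjusted over the list alone, median -0.17, camera adjusted p = 0.562, adjusted p = 0.787 with an estimated correlation). Guard cell and stomatal lineage markers fell in part, and 5 of 11 members fell (5 adjusted over the list alone, median -0.62, camera adjusted p = 0.00209, adjusted p = 0.0596 with an estimated correlation), with the potassium channel gene KAT1 at -2.62 ± 0.37. For the circadian clock 4 of 11 members rose and 1 fell (4 higher and 2 lower adjusted over the list alone, median 0.07, camera adjusted p = 0.298, adjusted p = 0.514 with an estimated correlation), with ELF4 at 1.38 ± 0.17, and for cell division 2 of 9 members fell (2 adjusted over the list alone, median -0.90, camera adjusted p = 0.122, adjusted p = 0.406 with an estimated correlation). For flower markers 2 of 5 members rose and 1 fell (2 higher and 1 lower adjusted over the list alone, median 1.77, camera adjusted p = 0.715, adjusted p = 0.832 with an estimated correlation). SEP3 (13.4-fold by 3 and 46 reads, 4.29 to 67.1) was one of them, and the sign of its fitted log2 fold change turned without WT drought 1 (-1.09, adjusted p = 0.664). Its call also ended without WT control 1 (adjusted p = 0.115), WT control 2 (0.110) or WT control 3 (0.0871). SOC1 was no longer past the threshold without WT control 1 (0.211), WT drought 1 (0.114) or WT drought 2 (0.0627). In the root marker list 1 of 1 measured members, PYK10, fell. It is a beta-glucosidase gene abundant in roots, which stood at 0.835 ± 0.507 CPM with water and at 0 under drought, a log2 fold change of -2.42 or lower against a floor of 3 reads (camera adjusted p = 0.467, adjusted p = 0.521 with an estimated correlation).

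In jar1-11 drought moved 10319 genes, 5071 higher and 5248 lower, 6557 with an absolute log2 fold change of at least 1. The late embryogenesis protein gene LEA7 rose from 2.38 ± 1.02 to 14326 ± 3561 CPM (log2 fold change 12.55 ± 1.18, adjusted p = 4.48e-08), and TIP1;2 changed by -6.93 ± 0.27. The arabinogalactan protein gene AGP7 fell (2375-fold by 1 and 2835 reads, 426 to 93835). From 0 reads in watered jar1-11, AT5G35660 rose at least 3089-fold, AT5G05220 at least 1844-fold, GASA3 at least 959.8-fold and the malic enzyme gene NADP-ME1 at least 783-fold. AT3G17520 rose as well (6583-fold by 3 and 16543 reads, 2252 to 31924). FLA2 (at least 593-fold), GASA9 (295-fold), EXPA8 (219-fold) and ACT (206-fold) fell to 0, and AT5G44020 fell to 1 read (2317-fold by 1 and 2766 reads, 416 to 91549.9).

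Of ABA and drought response genes 22 of 25 members rose and 2 fell (22 higher and 2 lower adjusted over the list alone, median 3.64, camera adjusted p = 1.89e-16, adjusted p = 0.0239 with an estimated correlation). All clade A PP2C phosphatases did (9 of 9 members, 9 adjusted over the list alone, median 5.24, camera adjusted p = 7.81e-15, adjusted p = 3.92e-04 with an estimated correlation), and HAI1 reached 575 ± 39.3 CPM. The raffinose synthase gene RS5 rose by 4.96 ± 0.31 and AAO3 by 3.0 ± 0.24. Photosynthesis fell as a group (33 of 34 members, 33 adjusted over the list alone, median -2.33, camera adjusted p = 1.59e-25, adjusted p = 0.0239 with an estimated correlation), with RBCS1A down from 4322 ± 599.7 to 270.2 ± 75.2 CPM and PSAN at -2.83 ± 0.17. For expansins 8 of 8 members fell (8 adjusted over the list alone, median -5.40 (-5.27 with genes at 0 reads at their bound), camera adjusted p = 2.43e-06, adjusted p = 0.0883 with an estimated correlation). For aquaporins 2 of 16 members rose and 13 fell (2 higher and 14 lower adjusted over the list alone, median -4.44 (-3.69 with genes at 0 reads at their bound), camera adjusted p = 5.23e-08, adjusted p = 0.0389 with an estimated correlation). Aliphatic glucosinolate genes fell (13 of 14 members, 13 adjusted over the list alone, median -2.87, camera adjusted p = 4.12e-07, adjusted p = 0.121 with an estimated correlation). Heat shock genes rose (8 of 8 members, 8 adjusted over the list alone, median 3.95, camera adjusted p = 1.08e-05, adjusted p = 0.0239 with an estimated correlation), with HSP70-4 at 5.45 ± 0.39. So did senescence genes (10 of 14 members rose and 1 fell, 10 higher and 2 lower adjusted over the list alone, median 2.42, camera adjusted p = 4.36e-05, adjusted p = 0.186 with an estimated correlation).

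Within the JA pathway of jar1-11, LOX2, which starts JA synthesis in wounded leaves, fell from 365 ± 43.4 to 4.29 ± 2.39 CPM (-6.45 ± 0.53), while ACX1, of a later step, rose by 2.36 ± 0.17. For JA biosynthesis as a whole 4 of 12 members rose and 5 fell (4 higher and 5 lower adjusted over the list alone, median -0.13, camera adjusted p = 0.736, adjusted p = 0.899 with an estimated correlation). In the MYC branch 2 of 12 members rose and 4 fell (2 higher and 3 lower adjusted over the list alone, median -0.12, camera adjusted p = 0.650, adjusted p = 0.825 with an estimated correlation). NAC019 rose (4.67 ± 0.29) and CLH1 fell (-4.77 ± 0.45). The repressor JAZ1 rose by 2.80 ± 0.44 and JAZ6 fell by 2.33 ± 0.43. The turnover genes ST2A (1.71 ± 0.32) and CYP94B3 (3.59 ± 0.70) rose. Of the JA-Ile and JA turnover genes 6 of 9 members rose (6 higher and 1 lower adjusted over the list alone, median 1.08, camera adjusted p = 0.162, adjusted p = 0.676 with an estimated correlation). Salicylic acid genes rose in most cases (11 of 18 members rose and 3 fell, 11 higher and 4 lower adjusted over the list alone, median 1.28, camera adjusted p = 0.104, adjusted p = 0.767 with an estimated correlation). NIMIN1 rose by 3.47 ± 0.46 and PAD3, of camalexin synthesis, reached 302 ± 202 CPM. The clock genes RVE8 (3.37 ± 0.35) and CCA1 (2.77 ± 0.36) rose as well.

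In JAR1-OE drought moved 5140 genes, of which 2497 were higher and 2643 lower, 2585 with an absolute log2 fold change of at least 1. VSP2 rose from 116 ± 38.0 to 3502 ± 1330.3 CPM (log2 fold change 4.92 ± 0.51, adjusted p = 7.45e-07), and the ABA marker RD29B by 6.91 ± 0.68. TSPO (7.01 ± 0.58), HIPP24 (253-fold by 2 and 531 reads, 69.8 to 2097), the heat shock factor gene HSFA6A (195-fold by 2 and 409 reads, 53.7 to 1617) and AT5G40790 (204-fold by 1 and 214 reads, 36.3 to 8103) were other large rises. GRP17, a pollen coat protein gene, also rose (7.41 ± 1.75), beside the flower transcripts of these libraries. GASA9 (1099-fold by 1 and 1049 reads, 197 to 43463), RL2 (460.1-fold by 1 and 439 reads, 82.1 to 18213), GRXS11 (291-fold by 1 and 278 reads, 51.9 to 11549), AT1G68238 (224-fold by 1 and 214 reads, 39.8 to 8899) and PDF1.2B (-7.11 ± 0.79) were among the largest falls, with ACT at least 69.5-fold lower at 0 reads.

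JA biosynthesis and MYC branch genes rose in JAR1-OE, and most ERF branch genes fell. For JA biosynthesis 9 of 12 members rose (9 adjusted over the list alone, median 1.29, camera adjusted p = 1.73e-04, adjusted p = 0.174 with an estimated correlation), with AOC2 at 700.3 ± 100.0 CPM against 242 ± 73.7. In the MYC branch 11 of 12 members rose (11 adjusted over the list alone, median 1.95, camera adjusted p = 3.05e-06, adjusted p = 0.0514 with an estimated correlation). In the ERF branch 1 of 7 members rose and 5 fell (1 higher and 5 lower adjusted over the list alone, median -3.12, camera adjusted p = 7.84e-04, adjusted p = 0.0781 with an estimated correlation). Of the JAZ repressors 3 of 11 members rose (3 adjusted over the list alone, median 0.59, camera adjusted p = 0.140, adjusted p = 0.556 with an estimated correlation). Among JA-Ile and JA turnover genes 1 of 9 members rose (1 adjusted over the list alone, median 0.65, camera adjusted p = 0.106, adjusted p = 0.528 with an estimated correlation). ABA and drought response genes rose (23 of 25 members, 24 adjusted over the list alone, median 2.82, camera adjusted p = 9.44e-36, adjusted p = 0.00161 with an estimated correlation). So did the clade A PP2C phosphatases (7 of 9 members rose, 7 adjusted over the list alone, median 2.88 (2.69 with genes at 0 reads at their bound), camera adjusted p = 6.12e-22, adjusted p = 4.24e-05 with an estimated correlation). All listed flavonoid genes rose (14 of 14 members, 14 adjusted over the list alone, median 2.71, camera adjusted p = 4.77e-13, adjusted p = 0.0213 with an estimated correlation). Photosynthesis genes fell in part (16 of 34 members, 18 adjusted over the list alone, median -0.46, camera adjusted p = 4.08e-06, adjusted p = 0.259 with an estimated correlation). PRODH1, of proline breakdown, fell by 4.92 ± 0.46. Aliphatic glucosinolate genes rose in part (6 of 14 members rose and 1 fell, 6 higher and 1 lower adjusted over the list alone, median 0.35, camera adjusted p = 0.173, adjusted p = 0.643 with an estimated correlation), with CYP79F1 at 1.18 ± 0.28. Flower markers rose in part (3 of 5 members, 5 adjusted over the list alone, median 2.74, camera adjusted p = 0.0260, adjusted p = 0.174 with an estimated correlation), of which AP3 lost its call without JAR1-OE control 1 (adjusted p = 0.0769), control 2 (0.0814), control 3 (0.123), drought 2 (0.122) or drought 3 (0.0584).

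Drought raised 1374 genes and lowered 1607 in all 3 genotypes. WT and jar1-11 shared 2539 raised and 2994 lowered genes, against 919.9 and 1109 for independent lists. WT and JAR1-OE shared 1570 and 1812 (453 and 559), and jar1-11 and JAR1-OE 1720 and 1982 (716 and 785). These contrasts share no library.

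**Figure D2:**
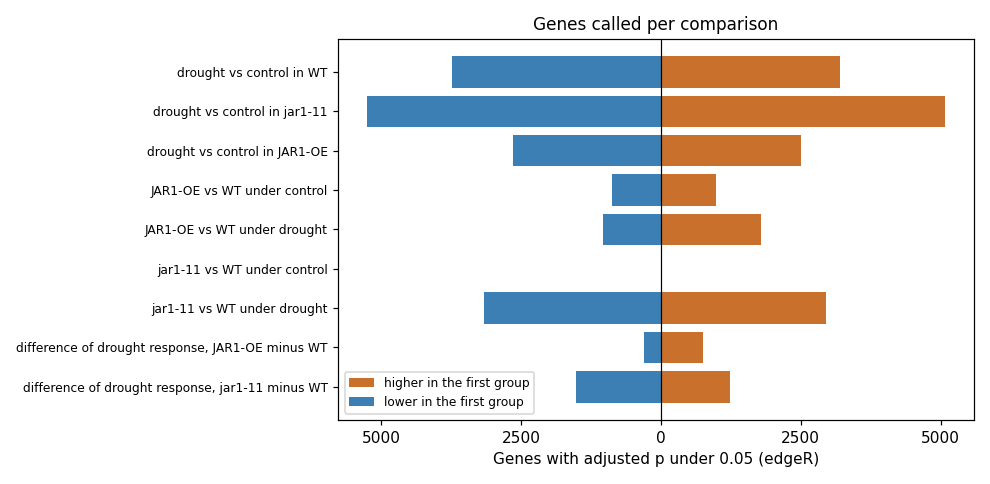
Number of genes called higher (to the right) and lower (to the left) at an adjusted p under 0.05 in each of the 9 comparisons, on a linear axis from 0, by edgeR's quasi-likelihood test over 17678 genes. Drought in jar1-11 gave 10319 genes, drought in JAR1-OE 5140, and jar1-11 against WT with water 1.

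With water, single genes differed between JAR1-OE and WT, while no list call held with an estimated correlation. VSP2 stood at 116 ± 38.0 CPM in JAR1-OE and 14.5 ± 2.89 in WT (log2 fold change 3.01 ± 0.49, adjusted p = 0.00164). The myrosinase genes TGG1 (1.99 ± 0.22) and TGG2 (1.59 ± 0.19), the cyclin gene CYCB1;2 (3.06 ± 0.49) and RBCS3B (1.53 ± 0.23) were higher. RD29A (96.4 ± 27.6 against 536 ± 318 CPM), ERD7 (-1.27 ± 0.19), HSP90.1 (-2.16 ± 0.37) and MYC4 (-1.02 ± 0.21) were lower. In total 1859 genes passed, 983 higher and 876 lower in JAR1-OE, so that 52.9% were higher (41.6% without WT control 3). That count rested on single libraries, with 556 genes without JAR1-OE control 1, 649 without JAR1-OE control 3 and 976 without WT control 1.

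The largest rises were AT4G22490 (5.86 ± 1.03), AT1G62500 (4.34 ± 0.71), the apyrase-family gene APY5 (3.95 ± 0.49), ATGRP9 (3.77 ± 0.41), AT3G16670 (3.67 ± 0.65; 2.45 without JAR1-OE control 1) and PDF1 (3.21 ± 0.61). The largest falls besides RD29A were AHP4 (-2.58 ± 0.47), the nitrilase gene NIT4 (-2.45 ± 0.43), AT1G80130 (-2.36 ± 0.38), CIPK25 (-2.33 ± 0.33) and the glutamine synthetase gene GLN1-4 (-2.29 ± 0.33). For photosynthesis 20 of 34 members were higher (24 adjusted over the list alone, median 0.67, camera adjusted p = 1.09e-16, adjusted p = 0.119 with an estimated correlation). For cell division 6 of 9 members were higher (8 adjusted over the list alone, median 1.3, camera adjusted p = 3.98e-08, adjusted p = 0.0858 with an estimated correlation). ABA and drought response genes were lower (12 of 25 members, 13 adjusted over the list alone, median -0.98, camera adjusted p = 6.17e-14, adjusted p = 0.0858 with an estimated correlation). So were clade A PP2C phosphatases (3 of 9 members were lower, 3 adjusted over the list alone, median -0.37, camera adjusted p = 0.00326, adjusted p = 0.103 with an estimated correlation; median -0.61 without WT control 3), with PP2CA at -1.16 ± 0.22. Flavonoid genes (6 of 14 members were lower, 7 adjusted over the list alone, median -0.89, camera adjusted p = 4.57e-05, adjusted p = 0.190 with an estimated correlation) were lower too. So were aliphatic glucosinolate genes (3 of 14 members, 4 adjusted over the list alone, median -0.57, camera adjusted p = 0.00178, adjusted p = 0.344 with an estimated correlation). In the JA MYC branch 5 of 12 members were higher and 1 was lower (6 higher and 2 lower adjusted over the list alone, median 0.49, camera adjusted p = 0.0241, adjusted p = 0.344 with an estimated correlation), a call that ended without WT control 2 (adjusted p = 0.0610) or WT control 3 (0.0921).

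Under drought JAR1-OE held more transcripts of the JA MYC branch, aliphatic glucosinolates, photosynthesis and aquaporins than WT and fewer of clade A PP2C phosphatases and heat shock genes. VSP2 stood at 3502 ± 1330.3 CPM against 89.3 ± 73.8 in WT (log2 fold change 5.30 ± 0.52, adjusted p = 2.70e-06). LOX2 was higher by 3.42 ± 0.43, BGLU18, a beta-glucosidase of leaf ER bodies, by 2.76 ± 0.49 and TIP1;2 by 2.64 ± 0.22. LEA4-5 (-2.65 ± 0.32), HB12 (-1.49 ± 0.16) and the pigment regulator MYB90 (-4.79 ± 0.52) were lower. In total 2814 genes passed, 1781 higher and 1033 lower, and with an absolute log2 fold change of at least 1 there were 1174 higher and 372 lower (63.3% and 75.9% higher). Without WT drought 3 the total was 1586 and without JAR1-OE drought 1 1814. With the flower marker score of each library as a covariate it was 1624.

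The largest rises besides VSP2 were APY5 (7.70 ± 0.59), AT1G66100 (6.51 ± 0.46), MSRB7 (5.31 ± 0.75), AT1G73325 (5.29 ± 0.71) and ATDR4 (4.77 ± 0.62). The largest falls besides MYB90 were AT4G31830 (-5.38 ± 0.47), AT5G35660 (-5.38 ± 0.55), AT2G42560 (-4.57 ± 0.66), NADP-ME1 (-4.45 ± 0.38) and CWINV5 (-4.44 ± 0.52). In the JA MYC branch 9 of 12 members were higher (11 adjusted over the list alone, median 1.96, camera adjusted p = 1.19e-08, adjusted p = 0.0316 with an estimated correlation). For JA biosynthesis 4 of 12 members were higher (4 adjusted over the list alone, median 0.45, camera adjusted p = 0.00229, adjusted p = 0.233 with an estimated correlation). The median of the latter was 0.94 without WT drought 2 and 0.25 without WT drought 3. All nuclear photosynthesis genes were higher (34 of 34 members, 34 adjusted over the list alone, median 1.36, camera adjusted p = 3.34e-41, adjusted p = 0.0282 with an estimated correlation), with LHCB3 at 2134 ± 93.6 against 519 ± 35.3 CPM. Aliphatic glucosinolate genes were higher (12 of 14 members, 12 adjusted over the list alone, median 1.35, camera adjusted p = 5.66e-12, adjusted p = 0.0350 with an estimated correlation). So were aquaporins (10 of 16 members were higher and 1 was lower, 13 higher and 1 lower adjusted over the list alone, median 1.33, camera adjusted p = 1.17e-08, adjusted p = 0.0350 with an estimated correlation). Expansins were higher (5 of 8 members, 6 adjusted over the list alone, median 1.76, camera adjusted p = 1.98e-07, adjusted p = 0.0402 with an estimated correlation), and so were cell division genes (8 of 9 members were higher, 9 adjusted over the list alone, median 2.13, camera adjusted p = 1.98e-07, adjusted p = 0.0316 with an estimated correlation). Guard cell markers were higher in part (3 of 11 members were higher, 3 adjusted over the list alone, median 0.73, camera adjusted p = 0.00112, adjusted p = 0.0375 with an estimated correlation).

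Lower in JAR1-OE than in WT were ABA and drought response genes (2 of 25 members were higher and 16 were lower, 3 higher and 17 lower adjusted over the list alone, median -1.02, camera adjusted p = 6.51e-09, adjusted p = 0.0632 with an estimated correlation). Clade A PP2C phosphatases were lower as well (5 of 9 members, 6 adjusted over the list alone, median -0.91, camera adjusted p = 1.26e-05, adjusted p = 0.0282 with an estimated correlation), and so were heat shock genes (3 of 8 members were lower, 3 adjusted over the list alone, median -1.1, camera adjusted p = 1.73e-04, adjusted p = 0.0350 with an estimated correlation). HAI1 stood at 129 ± 7.32 against 364 ± 66.8 CPM, and SWEET15 stood at 49.4 ± 17.9 against 163 ± 31.2 CPM. The ascorbate-recycling gene MDAR3 (3.66 ± 0.71) and VTC5, of ascorbate synthesis (1.34 ± 0.28), were higher. For flower markers 0 of 5 members passed (0 adjusted over the list alone, median 0.68, camera adjusted p = 0.250, adjusted p = 0.436 with an estimated correlation), WT drought 1 and the JAR1-OE libraries both holding such transcripts.

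With water, JAR1 was the only gene that differed between jar1-11 and WT by the edgeR test (1 of 17678 genes; 976 at an unadjusted p under 0.05). DESeq2 called 12 genes and limma-voom 1. Without both WT control 1 and WT drought 1 there were 11. Camera found small shifts of JA genes and of several other lists, none of which held with an estimated correlation. In the MYC branch 0 of 12 members passed (0 higher and 3 lower adjusted over the list alone, median -0.41, camera adjusted p = 1.85e-06, adjusted p = 0.103 with an estimated correlation). For the JAZ repressors 0 of 11 members passed (0 adjusted over the list alone, median -0.45, camera adjusted p = 2.09e-04, adjusted p = 0.231 with an estimated correlation). For JA-Ile and JA turnover 0 of 9 members passed (0 adjusted over the list alone, median -0.91, camera adjusted p = 7.40e-04, adjusted p = 0.231 with an estimated correlation; median -0.59 without jar1-11 control 1). ABA and drought response genes had a median of -0.21 (camera adjusted p = 0.00373, adjusted p = 0.411 with an estimated correlation). That call ended without WT control 3 (adjusted p = 0.249). Its median was -0.39 without WT control 2.

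Under drought 6105 genes differed between jar1-11 and WT, 2942 higher and 3163 lower in jar1-11 (3737 without jar1-11 drought 2). Single JA response genes were far lower in jar1-11. VSP2 stood at 1.68 ± 0.401 against 89.3 ± 73.8 CPM (log2 fold change -5.73 ± 0.62, adjusted p = 1.01e-05), BGLU18 at 8.63 ± 9.87 against 629 ± 404, and LOX2 differed by -4.69 ± 0.51. Salicylic acid genes such as WRKY70 (2.2 ± 0.35), SARD1 (2.54 ± 0.41) and NIMIN1 (2.64 ± 0.43) were higher, as were HSP17.4 (2.79 ± 0.29), the glutathione reductase gene GR1 (1.84 ± 0.18) and CAT2 (1.39 ± 0.18).

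PDF1.1 (6.08 ± 1.11), AT5G14330 (5.26 ± 0.74), XTH23 (4.81 ± 0.63), AT1G75600 (4.42 ± 0.58), AT1G53620 (4.23 ± 0.62) and SOM (4.22 ± 0.58) were the largest rises. VSP1 (-8.08 ± 1.33), THI2.1 (243-fold by 1 and 264 reads, 43.3 to 9645), RDL5_3 (88.9-fold by 2 and 193 reads, 24.3 to 739.5, and a fitted log2 fold change of -3.96 without WT drought 1), BGLU18 (-6.28 ± 0.61), F-ATMBP (-6.09 ± 0.89) and AT3G28220 (-6.04 ± 0.66; -10.01 without jar1-11 drought 3) were the largest falls. In the JA MYC branch 2 of 12 members were higher and 8 were lower (2 higher and 8 lower adjusted over the list alone, median -2.08, camera adjusted p = 3.40e-05, adjusted p = 0.126 with an estimated correlation). For JA biosynthesis 2 of 12 members were higher and 6 were lower (2 higher and 6 lower adjusted over the list alone, median -0.71, camera adjusted p = 0.0653, adjusted p = 0.590 with an estimated correlation). Salicylic acid and pathogenesis genes were higher (16 of 18 members, 16 adjusted over the list alone, median 2.35, camera adjusted p = 1.50e-07, adjusted p = 0.242 with an estimated correlation). So were heat shock genes (7 of 8 members were higher, 7 adjusted over the list alone, median 1.49, camera adjusted p = 3.91e-04, adjusted p = 0.119 with an estimated correlation). Clade A PP2C phosphatases were higher in part (5 of 9 members, 5 adjusted over the list alone, median 0.61, camera adjusted p = 0.00784, adjusted p = 0.119 with an estimated correlation). Senescence genes were higher (7 of 14 members, 8 adjusted over the list alone, median 0.87, camera adjusted p = 0.00132, adjusted p = 0.299 with an estimated correlation; median 0.56 without jar1-11 drought 1), with WRKY6 at 2.55 ± 0.35.

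Photosynthesis genes were lower in jar1-11 than in WT under drought (32 of 34 members were lower, 33 adjusted over the list alone, median -1.32, camera adjusted p = 4.09e-28, adjusted p = 0.119 with an estimated correlation), with LHCB6 at 84.8 ± 29.8 against 367 ± 61.2 CPM. So were aquaporins (1 of 16 members was higher and 11 were lower, 1 higher and 12 lower adjusted over the list alone, median -1.78, camera adjusted p = 9.80e-06, adjusted p = 0.126 with an estimated correlation). Expansins were lower (7 of 8 members, 8 adjusted over the list alone, median -3.32 (-2.86 with genes at 0 reads at their bound), camera adjusted p = 8.98e-05, adjusted p = 0.211 with an estimated correlation), and so were aliphatic glucosinolate genes (11 of 14 members, 11 adjusted over the list alone, median -1.37, camera adjusted p = 3.02e-05, adjusted p = 0.227 with an estimated correlation). TIP1;2 (-2.74 ± 0.23), EXPA4 (-3.42 ± 0.46) and the glucosinolate regulator MYB29 (-2.33 ± 0.33) were among them. The ABA and drought response genes went both ways (10 of 25 members were higher and 4 were lower, 10 higher and 4 lower adjusted over the list alone, median 0.60, camera adjusted p = 0.0176, adjusted p = 0.501 with an estimated correlation), a list call that ended without jar1-11 drought 1 (adjusted p = 0.0636). DREB2A was higher (1.88 ± 0.26) and ABF3 lower (-1.29 ± 0.20). The flower genes PI (-4.17 ± 1.38), SEP3 (21.2-fold by 2 and 46 reads, 5.54 to 180.2) and AP3 (26.7-fold by 1 and 29 reads, 4.43 to 1091) were called lower, and their fitted log2 fold changes changed sign without WT drought 1, with no call left (1.92, 0.53 and 1.96). The calls also ended without jar1-11 drought 1 (adjusted p = 0.0786, 0.111 and 0.121) or jar1-11 drought 2 (0.0672, 0.141 and 0.154), and without jar1-11 drought 3 for PI (0.0617) and AP3 (0.0562), where SEP3 had a fitted log2 fold change of -7.10.

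Against WT under drought the genotypes moved apart. 914 genes were higher in JAR1-OE and lower in jar1-11, and 436 the reverse (319 and 172 for independent lists), against 118 higher and 28 lower in both. Across genes, which are not independent replicates, the fold changes of the genotypes had r = -0.369 and a covariance of -0.356. Unchanged groups simulated against the same WT libraries gave r = 0.498 and a covariance of 0.0779 over 20 simulations, so the shared libraries act in the other direction.

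**Figure D3:**
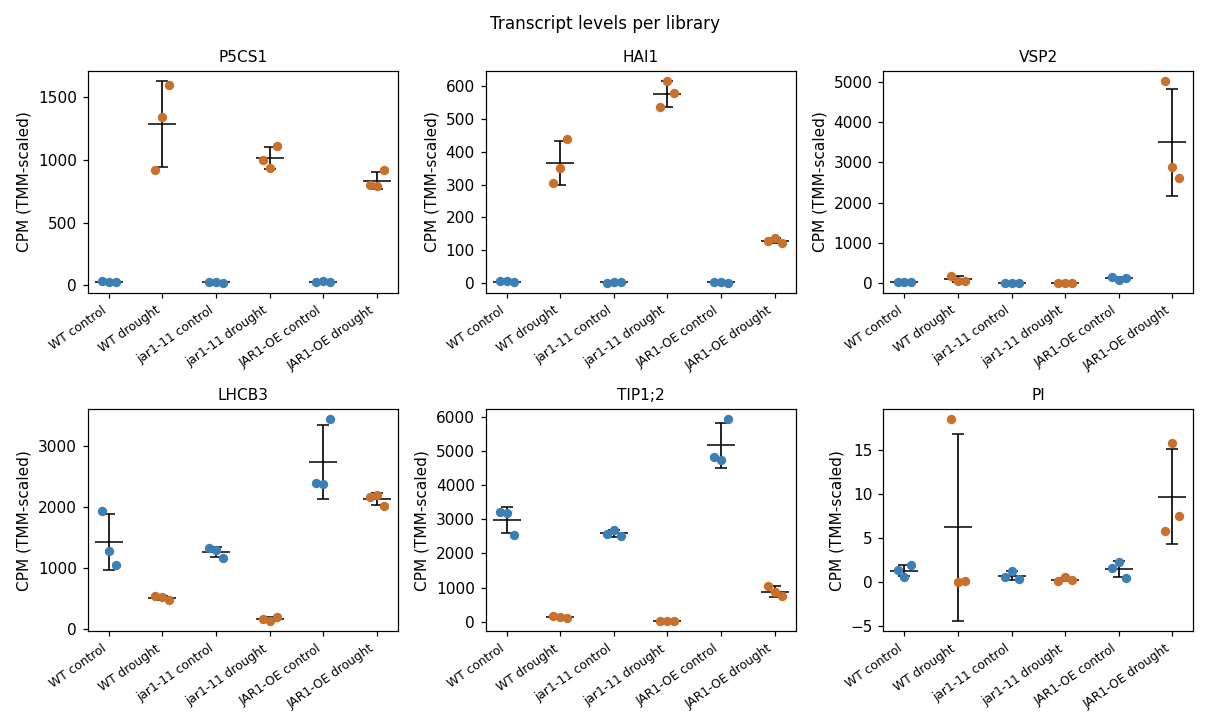
Level in CPM of 6 genes in each library by group, with dashes at group means and error bars of 1 SD (n = 3), on linear axes. P5CS1 and HAI1 rise with drought in each genotype, VSP2 reaches 3502 ± 1330.3 CPM in JAR1-OE under drought, and PI is present in WT drought 1 and the JAR1-OE drought libraries.

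Whether drought acted differently in JAR1-OE than in WT was tested as a difference of responses. LOX2 (3.24 ± 0.57, adjusted p = 0.00260) and AOS (2.04 ± 0.45) of JA synthesis, CLH1 (2.40 ± 0.47) and MYC4 (1.82 ± 0.30) responded more positively in JAR1-OE. So did the glucosinolate genes CYP79F1 (3.58 ± 0.41), MAM3 (3.65 ± 0.56) and BAT5 (2.61 ± 0.41), the aquaporins PIP2;2 (2.2 ± 0.33), TIP2;2 (2.24 ± 0.34) and TIP1;2 (1.84 ± 0.29), and COR15B (3.19 ± 0.37). HB12 (-1.59 ± 0.24) responded less, while its list as a whole was not called. Of the ABA and drought response genes 3 of 25 members were higher and 1 was lower (6 higher and 2 lower adjusted over the list alone, median -0.04, camera adjusted p = 0.689, adjusted p = 0.883 with an estimated correlation). Of the clade A PP2C phosphatases 0 of 9 members passed (0 adjusted over the list alone, median -0.29 (-0.10 with genes at 0 reads at their bound), camera adjusted p = 0.689, adjusted p = 0.869 with an estimated correlation). In total 1062 genes differed, 752 more positive and 310 more negative in JAR1-OE. For aliphatic glucosinolates 11 of 14 members were higher (11 adjusted over the list alone, median 1.77, camera adjusted p = 2.55e-18, adjusted p = 0.0558 with an estimated correlation). For photosynthesis 10 of 34 members were higher (14 adjusted over the list alone, median 0.58, camera adjusted p = 2.74e-07, adjusted p = 0.430 with an estimated correlation). In the JA MYC branch 3 of 12 members were higher (5 adjusted over the list alone, median 0.90, camera adjusted p = 0.00175, adjusted p = 0.397 with an estimated correlation). The difference of VSP2 lost its call in 9 of 12 omissions of 1 library. For JA biosynthesis 4 of 12 members were higher (5 adjusted over the list alone, median 0.93, camera adjusted p = 1.61e-04, adjusted p = 0.397 with an estimated correlation). The count was 627 without WT drought 2, 578 without WT drought 3, 577 without JAR1-OE control 1, 569 without JAR1-OE control 3, 631 without JAR1-OE drought 1 and 624 without JAR1-OE drought 2. It was 616 with the flower marker score.

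In jar1-11 the difference from the WT response took in 2761 genes, 1235 more positive and 1526 more negative. BGLU18 (-6.45 ± 0.74, adjusted p = 1.37e-04) and CLH1 (-3.34 ± 0.56) of the JA response and LOX2 (-4.43 ± 0.63) and AOC2 (-1.42 ± 0.36) of JA synthesis responded more negatively. ACX1, of JA synthesis as well, responded more positively (1.43 ± 0.23). RD26 (2.26 ± 0.39), RD20 (2.15 ± 0.39) and COR47 (1.70 ± 0.28) of the drought response, SARD1 (2.61 ± 0.57), WRKY70 (2.04 ± 0.47) and GR1 (1.74 ± 0.27) responded more positively. TIP1;2 (-2.54 ± 0.30), EXPA4 (-3.32 ± 0.53), LHCB6 (-2.14 ± 0.31) and BAT5 (-2.52 ± 0.52) responded more negatively. In the ABA and drought response list 10 of 25 members were higher and 2 were lower (11 higher and 4 lower adjusted over the list alone, median 0.75, camera adjusted p = 4.69e-04, adjusted p = 0.314 with an estimated correlation). For photosynthesis 28 of 34 members were lower (30 adjusted over the list alone, median -1.21, camera adjusted p = 2.57e-23, adjusted p = 0.135 with an estimated correlation). For salicylic acid genes 6 of 18 members were higher (10 adjusted over the list alone, median 2.06, camera adjusted p = 8.26e-06, adjusted p = 0.314 with an estimated correlation; median 1.22 without jar1-11 drought 2). In the JA MYC branch 1 of 12 members was higher and 5 were lower (2 higher and 7 lower adjusted over the list alone, median -1.36, camera adjusted p = 0.00956, adjusted p = 0.314 with an estimated correlation). The count was 1458 without jar1-11 drought 2, 1704 without WT drought 1 and 1763 without jar1-11 control 2.

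**Figure D4:**
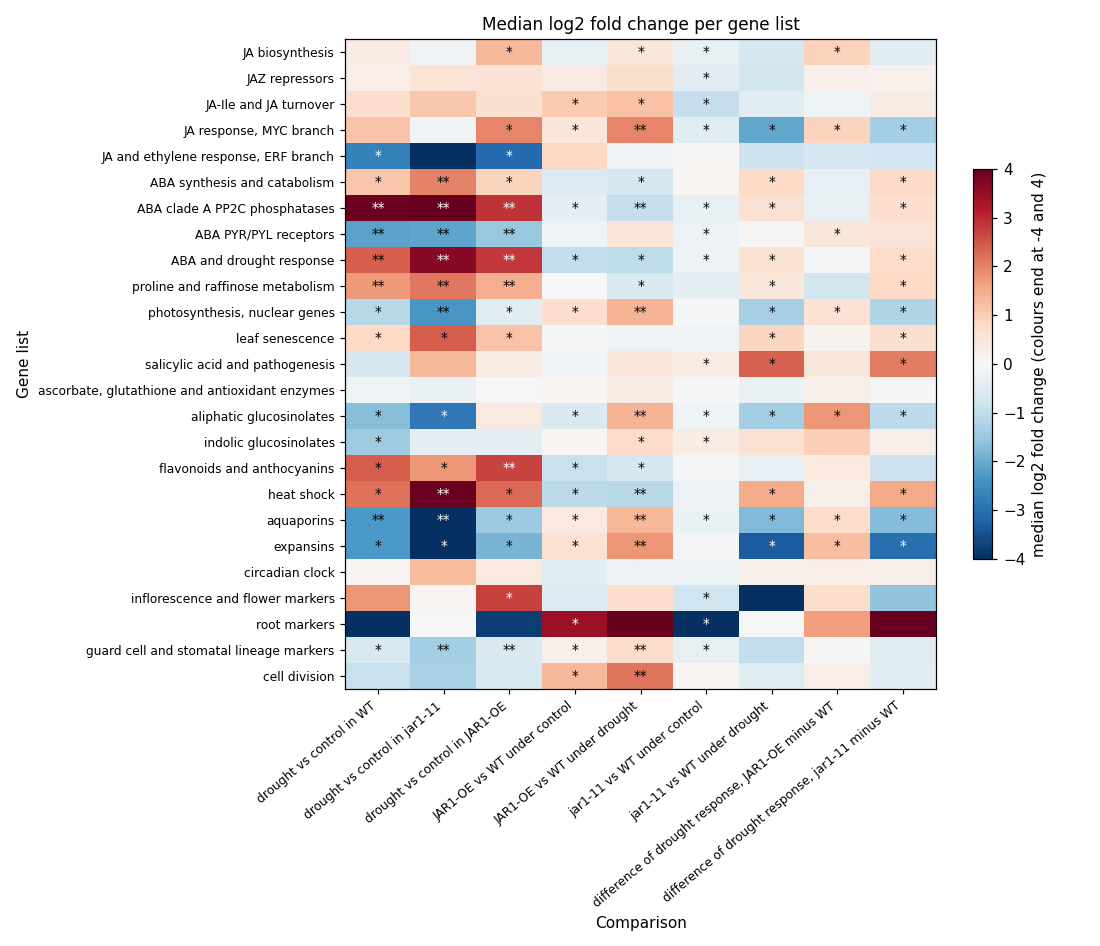
Median log2 fold change of each of the 25 gene lists (1 gene for root markers) in each of the 9 comparisons, as a colour from blue (lower) to red (higher). 1 star marks a camera adjusted p under 0.05 with the preset correlation and 2 stars one that also holds with an estimated correlation. The photosynthesis list goes from 1.36 in JAR1-OE against WT under drought to -1.32 in jar1-11 against WT.

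The size of the drought response was compared over genes that drought had changed in the remaining genotype, at an adjusted p under 0.05 and an absolute log2 fold change of at least 1, so that neither genotype compared chose them. Over 2916 genes raised by drought in jar1-11, the median log2 fold change was 0.69 in JAR1-OE and 1.01 in WT. Over 3641 genes lowered in jar1-11 it was -0.62 and -1.13. The difference of response had medians of -0.36 (camera adjusted p = 2.27e-10, adjusted p = 0.0452 with an estimated correlation) and 0.54 (3.47e-21 and 0.0181), and the slope of JAR1-OE on WT was 0.610. Over the 1247 raised and 1338 lowered genes of JAR1-OE, jar1-11 reached 1.95 and -2.43, and WT 1.61 and -2.01. There the difference had medians of 0.30 (6.34e-05, and 0.0315 with an estimated correlation) and -0.58 (1.84e-05, and 0.112 with an estimated correlation), with a slope of 1.15.

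Each of these 4 medians kept its call without any 1 library, but their sizes moved. Over the gene sets above, the flower marker score as a covariate gave -0.21 and 0.45 for JAR1-OE and 0.30 and -0.49 for jar1-11. In the settings that follow the sets were drawn again from each fit. With the flower marker score the medians were then -0.22 and 0.45 for JAR1-OE and 0.45 and -0.62 for jar1-11, so that the rise from 0.30 to 0.45 came with the change of genes. With the 200 genes of smallest p those of JAR1-OE were -0.79 and 1.06. In jar1-11 the 0.30 was 0.20 without WT control 3. The -0.58 was -0.38 without WT drought 1, and -0.32 without both WT control 1 and WT drought 1. With genes at 0 reads in a group at their bound, in the sets above, the 4 medians were -0.33, 0.53, 0.25 and -0.49.

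Per library, the slope on the response of the genotype left out was 0.375 ± 0.0147 (SD, n = 3) in JAR1-OE and 0.612 ± 0.105 in WT, and 1.2 ± 0.0258 in jar1-11 and 1.05 ± 0.0620 in WT. The libraries did not overlap in either comparison, and the 2-sided exact permutation p was 0.10 for each, the smallest that 3 against 3 can give. With water, the genes raised by drought had a median of -0.07 in JAR1-OE against WT (camera adjusted p = 0.0206, adjusted p = 0.511 with an estimated correlation) and the lowered ones 0.20 (0.00105 and 0.434). In watered jar1-11 the medians were -0.13 (0.00439 and 0.247) and -6.30e-05 (0.725 and 0.888). The calls of the raised genes rested on single libraries. That of JAR1-OE ended without WT control 2 (adjusted p = 0.0747) or WT control 3 (0.0879), and that of jar1-11 without WT control 3 (0.0879) or jar1-11 control 2 (0.0556). The lowered genes of jar1-11 gained a call without jar1-11 control 3 (0.0446).

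**Figure D5:**
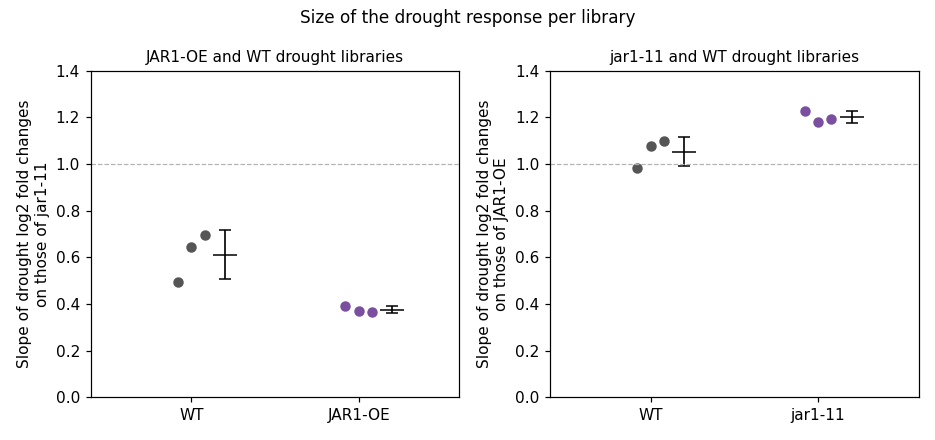
Slope of each drought library's response on the response of the genotype left out of the comparison, by genotype. Points are drought libraries, each set against the mean of its genotype's 3 watered libraries. Dashes are the mean and error bars the SD of 3 libraries, and the dashed line marks a slope of 1. JAR1-OE lies at 0.375 against 0.612 in WT, and jar1-11 at 1.2 against 1.05.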

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

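Tests chosen only after the data were seen were the flower score covariate, the carry-over test, the comparison of MYC branch genes in JAR1-OE under drought with both WT groups, the test of a single scaled drought response with its noise correction, and the omission of GRP17 from the flower gene count.

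Differences of the drought response between genotypes met the condition for a closer look by their own test. In JAR1-OE 1062 genes differed from WT. The largest fitted differences, in log2 units, were AZI1 (5.86), AT5G02760 (5.12), AT5G56840 (5.0), AT4G12490 (4.91) and AT1G27020 (4.56) upward and AKR4C9 (-4.92), AT4G25433 (-4.87), ATDI21 (-3.76), THA1 (-3.75) and EGY3 (-3.63) downward. AZI1 and AT5G02760 had 0 reads in WT drought, so that their fitted values are no measure of size, and against a floor of 3 reads the bounds are 2.92 for AZI1 and 2.18 for AT5G02760. Resting on 1 to 3 reads in a group, with the reads and the 95% counting limits, were AT5G56840 (1 in WT drought, 3.04 to 10.82), AT4G12490 (2 in WT drought, 3.31 to 8.20), AKR4C9 (2 in WT control, -8.16 to -3.26) and AT4G25433 (1 in WT control, -10.55 to -2.77). Of the 10 genes AT5G56840, AT1G27020, ATDI21, THA1 and EGY3 kept their calls without any 1 library. The adjusted p of the others passed 0.05 without JAR1-OE control 1 (AT5G02760 0.0748, AKR4C9 0.153, AT4G25433 0.256), JAR1-OE control 2 (AT5G02760 0.0540), JAR1-OE control 3 (AZI1 0.0585, AT5G02760 0.0710, AT4G12490 0.0558), JAR1-OE drought 1 (AT5G02760 0.118), JAR1-OE drought 2 (AZI1 0.0650, AT4G12490 0.0531), JAR1-OE drought 3 (AZI1 0.0698, AT4G12490 0.0529), WT control 1 (AT4G25433 0.0587), WT drought 1 (AZI1 0.0522, AT5G02760 0.0625, AT4G12490 0.0504), WT drought 2 (AZI1 0.0855, AT5G02760 0.101, AT4G12490 0.0560 (log2 difference 7.55)) and WT drought 3 (AZI1 0.0831, AT5G02760 0.0957, AT4G12490 0.0847).

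In jar1-11 2761 genes differed from WT in their drought response. The largest fitted differences were RAP2-6 (7.71), AT5G14330 (4.99), UGT74E2 (4.93), AT1G30700 (4.77) and NTL8 (4.74) upward and PDF1.2C (-8.47), THI2.1 (-7.93), AT5G50335 (-7.24), FLA12 (-6.93) and JAL23 (-6.52) downward, in log2 units. RAP2-6 had 0 reads in jar1-11 control and AT5G50335, FLA12 and JAL23 had 0 reads in jar1-11 drought, so that their fitted values are no measure of size, and against a floor of 3 reads the bounds are 4.79 for RAP2-6, -4.09 for AT5G50335, -3.71 for FLA12 and -3.35 for JAL23. Resting on 1 to 3 reads in a group, with the reads and the 95% counting limits, were UGT74E2 (3 in jar1-11 control, 3.63 to 7.46), NTL8 (2 in jar1-11 control, 3.14 to 8.04), PDF1.2C (1 in jar1-11 drought, -13.85 to -6.06) and THI2.1 (1 in jar1-11 drought, -13.51 to -5.72). UGT74E2 and THI2.1 kept their calls without any 1 library. The adjusted p of the others passed 0.05, unless another value is given, without WT control 1 (RAP2-6 0.124, AT1G30700 0.0801, NTL8 0.0536), WT control 2 (AT5G14330 0.218, AT1G30700 0.124, NTL8 0.0668), WT control 3 (RAP2-6 0.180, AT1G30700 0.0702), WT drought 1 (AT1G30700 0.0881, JAL23 0.0552, PDF1.2C 0.130 (log2 difference -5.50)), WT drought 3 (RAP2-6 0.0534, AT1G30700 0.0644), jar1-11 control 1 (RAP2-6 0.0847, AT1G30700 0.0908, NTL8 7.22 on the log2 scale), jar1-11 control 2 (RAP2-6 0.0781, AT1G30700 0.0883, NTL8 0.0661, JAL23 0.0503), jar1-11 control 3 (RAP2-6 0.0637, AT1G30700 0.0713, NTL8 0.0519), jar1-11 drought 1 (RAP2-6 0.0527, JAL23 0.0613), jar1-11 drought 2 (RAP2-6 0.0654, AT1G30700 0.104, NTL8 0.0567, PDF1.2C 0.0525, AT5G50335 0.0538, FLA12 0.0584, JAL23 0.0950) and jar1-11 drought 3 (AT1G30700 0.0509). A signal outside the tested genes was the YFP-JAR1 entry, at 28.8 CPM over the watered and 34.6 CPM over the drought JAR1-OE libraries, with 0 reads in the other 12 libraries.

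In the MYC branch of the JA response, the members had a median log2 fold change of 1.96 in JAR1-OE against WT under drought. Flower tissue in the harvest would remove much of this when the flower score is held as a covariate, but the median stayed at 1.93 and 8 of 12 members stayed called. The score itself was called for 100 genes, and the genes called in this comparison went from 2814 to 1624, a fall that a covariate partly aligned with the groups can give by itself. For a milder drought as the sole explanation, the drought response of jar1-11 was subtracted, which left a median of 1.42, against -0.17 and 0.21 as the bounds of the central 95% of 10000 random lists of equal size and like expression. Under drought in jar1-11 these members go both ways (median -0.12, against 1.13 in WT). The subtraction thus predicts no shift of the list and cannot tell a milder drought apart. A milder drought on a steady course from watered to dry WT would leave JAR1-OE between the WT groups. Of the 12 members 8 were called above both, as were 262 of all 17678 genes tested, and the members had a median of 1.47 log2 units above the higher WT group. The bounds set were at most 2 members for such a course and at least 7 against it. Without 1 library of WT or of JAR1-OE under drought the counts were 5 to 9 and the medians 1.08 to 1.80, the lowest of both without JAR1-OE drought 1, where the count lay between the bounds. With all libraries the count passed the bound against a steady course. The bounds, written after the data were seen, take JAR1-OE to start at watered WT. With water 5 of 12 members were already higher and 1 was lower in JAR1-OE than in WT (median 0.49). The count thus cannot tell a milder drought from a higher starting level. In WT drought raised 7 of the 12 members, and for these a level above dry WT also means one above watered WT. A transcript that peaks at mild drought and a developmental difference between the lines stay open and untested. Levels did differ by genotype, as jar1-11 under drought had 2 members higher and 8 lower than WT.

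The weaker drought response in JAR1-OE (median differences -0.36 and 0.54 over genes raised and lowered by drought) and the stronger one in jar1-11 (0.30 and -0.58) were weighed against depth and flower tissue. With every library thinned to the lowest total, 2510 genes differed in JAR1-OE against WT under drought (from 2814), and 5558 in jar1-11 (from 6105), and the 4 medians kept their signs, which argues against depth. The lowest ratio of the 4 medians with the flower score to those without, over the same sets, was 0.603, above the bound of 0.5. A single drought response scaled alike in every gene would make r squared across genes, which are not independent replicates, exceed 0.8. It was 0.403 for JAR1-OE (0.629 after correction for noise over 11884 genes), under the bound of 0.5 set against it. That bound ignored noise, so this explanation cannot be told apart there. For jar1-11, set against the response of JAR1-OE, r squared was 0.0264 (0.0640), which argues against 1 such response common to all 3 genotypes. The response of JAR1-OE went another way in part, as aliphatic glucosinolates had medians of 0.35 there, -1.70 in WT and -2.87 in jar1-11. The r squared thus does not settle whether jar1-11 differs from WT by scale alone. How dry the plants were is not given and stays open.

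Flower transcripts stood out in WT drought 1 and the JAR1-OE drought libraries. Of 15 flower genes listed separately 12 had at least 10 reads over all libraries, and 11 were counted after leaving out GRP17, which had first been noticed in the comparisons. All 11 of these were highest in WT drought 1 among the WT drought libraries, which flower tissue in the harvest needs. Such genes vary together, so they do not count as independent. Only 1 of the 12 passed 1 CPM in jar1-11 or watered libraries. Carry-over from JAR1-OE drought 1, 2 or 3 into WT drought 1 would need a share of 3.55, 1.05 or 2.65 of the library for its PI and SEP3 levels, which no share up to 1 can give. Even with WT drought 1 made up of such a library in whole, at least 22.3 YFP-JAR1 reads were expected and 0 were seen, and VSP2 would reach at least 2602 CPM against 174 observed. Earlier flowering of these plants or a less strict removal of stems could give such transcripts, and neither was tested.

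Each real grouping was set against other splits of the same samples. For comparisons of 2 groups there are 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes in each. The real count and the highest of the other splits were, in order, drought vs control in WT (6943 and 1), drought vs control in jar1-11 (10319 and 0), drought vs control in JAR1-OE (5140 and 0), JAR1-OE vs WT under control (1859 and 0), JAR1-OE vs WT under drought (2814 and 3), jar1-11 vs WT under control (1 and 0), jar1-11 vs WT under drought (6105 and 0). For the difference of response in JAR1-OE 3 of 100 splits gave as many genes as the real one (1062, highest other 3393), a share under 0.05. For jar1-11 9 of 100 did (2761, highest other 3967), so chance cannot be excluded by this test. These were 3 of the 11 and 9 of the 12 splits that kept the real genotypes of the drought libraries, the real ones included, and the others mixed those of the watered ones. Splits that also mix drought libraries thus make up most of the 100, and the share under 0.05 speaks to the grouping of the drought libraries and not to that of the watered ones. The high count of the other splits points to a structure of the samples, since the drought libraries differ by genotype whichever way the watered ones are mixed.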

How the results depend on the processing

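Tests chosen only after the data were seen were leaving out WT control 1 and WT drought 1 together and the flower score covariate. Without 1 library at a time, counts of called genes ran from 5661 to 6706 for drought in WT, 9209 to 9897 in jar1-11 and 3951 to 4328 in JAR1-OE. For JAR1-OE against WT they ran from 556 to 2054 with water and 1586 to 3023 under drought, and for jar1-11 against WT under drought from 3737 to 5926. For jar1-11 against WT with water the lowest and highest were 1 and 1. The differences of response ran from 569 to 1418 in JAR1-OE and 1458 to 3074 in jar1-11. Fewer libraries give less power by construction, and the cause of each shift was not tested.

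Medians over the genes raised and lowered by drought ran, with water, from -0.0969 to -0.0525 and 0.17 to 0.20 in JAR1-OE against WT, and from -0.18 to -0.0814 and -0.0489 to 0.0637 in jar1-11. For the difference of response they ran from -0.47 to -0.27 and 0.43 to 0.71, with slopes of 0.537 to 0.622, in JAR1-OE, and from 0.20 to 0.32 and -0.66 to -0.38, with slopes of 1.09 to 1.16, in jar1-11.

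With an absolute log2 fold change of at least 1 the counts were 3950, 6557 and 2585 for drought in WT, jar1-11 and JAR1-OE, 777 and 1546 for JAR1-OE against WT with water and under drought, and 3287 for jar1-11 against WT under drought. DESeq2 gave 12 genes for jar1-11 against WT with water and 1645 for the difference of response in JAR1-OE. A fit of only the groups compared gave 927 for JAR1-OE against WT with water and 2 for jar1-11. The top 200 genes gave a slope of 0.673 for JAR1-OE. The cause was not tested.

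Without WT control 1 and WT drought 1 the counts were 1198 for JAR1-OE and 11 for jar1-11 against WT with water, and the slopes 0.539 and 1.08. With the flower score they were 1624 for JAR1-OE against WT under drought, 4 for jar1-11 against WT with water and 616 for the difference in JAR1-OE, and the slopes 0.672 and 1.2. Flower genes turned sign without WT drought 1, so that leaving out 1 library at a time gave -1.09 to 4.50 for SEP3 in WT drought, and -4.97 to 1.92 for PI, -7.10 to 0.53 for SEP3 and -6.43 to 1.96 for AP3 in jar1-11 against WT under drought. Without both WT libraries the values were -1.49, 1.92, 0.53 and 1.98 in the same order. WT drought 1 held most reads of these genes among the WT drought libraries.

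With a replicate block the counts were 6667, 10099, 4896, 1434, 2552, 1, 5787, 852 and 2443 in the order of drought in WT, jar1-11 and JAR1-OE, JAR1-OE against WT with water and under drought, jar1-11 against WT likewise, and the differences in JAR1-OE and jar1-11, and 13 named genes lost their calls and 0 lists did. Between control and drought, equal replicate numbers follow from order alone, since the labels' own numbers run on. No groups had all 3 pairs of equal replicate numbers correlate above 0.1. All 3 libraries correlated best with their own number only between jar1-11 drought and WT control (0.110, 0.125 and 0.0328), which only the difference of response sets together, so the numbers were not taken as pairs. Of the calls of named genes DESeq2 kept 531 and lost 7, limma-voom kept 508 and lost 30, RLE scaling lost 1, no filter 3, a fit of only the groups compared 38, no organelle genes 1, the omission of both WT libraries 39 and the flower score 34. The omission of both WT libraries ended 10 list calls and the flower score 6, namely indolic glucosinolates in WT drought (adjusted p = 0.0698), flower markers in JAR1-OE drought (adjusted p = 0.433), guard cell markers in JAR1-OE drought (adjusted p = 0.119), proline and raffinose metabolism in JAR1-OE against WT under drought (adjusted p = 0.123), PYR/PYL receptors in the difference of JAR1-OE (adjusted p = 0.0833) and expansins in the difference of JAR1-OE (adjusted p = 0.0733). Of the list calls 29 held with an estimated correlation and 89 did not. Only reads mapped to 1 place are used here, so the alternative of all reads was not run. In the simulated data 17 of 54 genes changed 2-fold were recovered below a mean of 14.9 CPM and 26 of 44 above it, so 2-fold changes of low genes are often missed at these depths.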

Other observations

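Flavonoid genes rose under drought in jar1-11 too, where 13 of 14 members rose (13 adjusted over the list alone, median 1.76, camera adjusted p = 6.95e-04, adjusted p = 0.205 with an estimated correlation). For guard cell and stomatal lineage markers 8 of 11 members fell (8 adjusted over the list alone, median -1.36, camera adjusted p = 0.00375, adjusted p = 0.0487 with an estimated correlation). For cell division 5 of 9 members fell (5 adjusted over the list alone, median -1.29, camera adjusted p = 0.162, adjusted p = 0.514 with an estimated correlation).

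The beta-glucosidase gene PYK10 stood at 8.75 ± 4.82 CPM in watered JAR1-OE and 0.835 ± 0.507 in watered WT (log2 fold change 3.43 ± 0.63, edgeR adjusted p = 0.00629), and had 0 reads in all 6 jar1-11 libraries. Between jar1-11 and WT with water it was not called (adjusted p = 0.867), with WT at least 5.90-fold higher. Under drought it stood at 0.641 ± 0.359 CPM in JAR1-OE and had 0 reads in WT. No explanation was tested.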
